A study of Mus musculus with 6 samples.

How the data were processed

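MicroRNAs (miRNAs, short RNAs that repress messenger RNAs) were measured in left ventricle tissue of male C57BL/6 mice that received sunitinib or vehicle, with 3 samples in each group. Per the labels, each sample was hybridised alone, in Cy3, to an Agilent mouse miRNA array, from 200 ng of total RNA. The arrays hold 1881 mouse miRNAs on 4415 probes and 56430 spots. Groups and replicate numbers came from the sample titles. The labels do not say outright that each sample came from its own animal, so p-values measure only the spread between these samples, which may in part be technical.

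The deposited scanner files give spot intensity on a linear scale, already background-subtracted by Agilent Feature Extraction, per the file headers and the submitters' processing notes, which name version 10.7. The file headers give version 10.7.1.1 and genome build mm9. The headers also say that a spot counts as well above background where it exceeds its background by 13 times the background SD. The deposited value table holds log2 values of the same arrays with the authors' processing, whose scale and centring are not given in the sources used here. Its columns have medians of 2.196, 2.195 and 2.196 in control and 2.199, 2.200 and 2.196 in sunitinib replicates 1 to 3. Each column's differences between arrays correlated best with those of its own array's scanner values (Pearson r across miRNAs from 0.919 to 0.954). That table served only as an alternative.

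Spots flagged as non-uniform or population outliers were left out, as were control spots. Each array's processed signal was divided by a factor that aligned the 75th percentile of log2 signal over the 393 probes well above background on all 6 arrays. The scaled signal was then floored at 1, put on the log2 scale and averaged over the spots of a probe. A probe was taken as well above background on an array where at least 50% of its spots were. The probe with the highest mean stood for its miRNA. A miRNA was tested if well above background on all 3 arrays of at least 1 group, which left 237 miRNAs. Sunitinib was compared with control by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested miRNAs and a threshold of 0.05. All p-values of single miRNAs below are from this limma fit. Of 165 miRNAs with at least 2 probes well above background on all arrays, the brightest and the next brightest probe changed in the same direction in 142.

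Before the data were examined, 17 miRNA lists were fixed, along with the design, most of the alternatives and the rule for the miRNAs named. The rule takes miR-146a-5p, miR-146a-3p and miR-146b-5p in any case. It adds up to 10 miRNAs per direction past the threshold whose groups do not overlap, filled up to 5 by the smallest unadjusted p. It also takes up to 4 measured members of each list by unadjusted p. Lists with at least 3 tested members were tested with limma's camera (preset correlation 0.01), with camera's estimated correlation and with fry as alternatives. The list of miRNAs numbered 1000 or higher stands for late-annotated miRNAs. Where every probe of a miRNA was not well above background on all arrays of a group, the difference is given as a bound. The bound sets the bright group's mean against the mean, per array, of the higher of the dim probe's own value and the lowest value among probes well above background.

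The fit was tested on simulated data for this comparison, with the 237 tested miRNAs, their measured spread and 20 changed miRNAs in each of 50 runs. It recovered 72.3% of changes of 1.5-fold, 91.9% of changes of 2-fold and 98.3% of changes of 4-fold. False calls averaged 0.9, 1.02 and 1.22 per run at these sizes, and 0.06 with no change simulated. The noise was drawn independently for each miRNA on scaled values. Effects shared by an array or a slide row, and errors of scaling, were thus not simulated, and the false calls in the real data may be more. Alternatives covered the background correction, scaling, probe summary, filter, floor, variance model, array weights, a block for replicate number or slide row, and leaving out each sample. The normexp background correction adds an offset of 50 to the signal, which by construction pulls log2 changes of dim miRNAs toward 0. The number of arrays limits the precision. Neighbouring genes were named from the RefSeq table of assembly GRCm38.p6, whose coordinates differ from mm9 and are not printed.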

Results

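The series title names miR-146a and heart dysfunction under sunitinib, a tyrosine kinase inhibitor given against cancer, and the arrays compare left ventricles of sunitinib-treated mice with those of vehicle-treated mice. All 6 arrays lay on 1 slide and no spot was saturated. Control arrays had 241, 252 and 237 miRNAs well above background, and sunitinib arrays 240, 234 and 242. The means, 243.3 ± 7.77 and 238.7 ± 4.16 (SD, n = 3 each), were not told apart by an exact two-sided permutation test (p = 0.5, where the smallest p that 3 against 3 samples allow is 0.1). Within groups, the SD of log2 differences between 2 arrays ran from 0.177 to 0.410. Between groups it ran from 0.33 to 0.48, so the ranges overlapped.

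In sunitinib hearts, miR-223-3p, a miRNA abundant in neutrophils and other myeloid cells, fell from 8.32 ± 0.13 to 6.996 ± 0.077 on the log2 scale (SD, n = 3 each), a 2.50-fold decrease. miR-142a-3p, which blood-forming cells express, fell 1.56-fold, and miR-511-3p, which lies within the macrophage mannose receptor gene Mrc1, was at least 2.16-fold lower. miR-532-5p fell 1.45-fold. In the other direction, miR-3960, miR-5126, miR-2861 and the hypoxia-responsive miR-210-3p rose by 1.70-fold, 1.56-fold, 1.29-fold and 1.29-fold. These 8 of 237 tested miRNAs, 4 higher and 4 lower, passed an adjusted p of 0.05, and at an unadjusted p under 0.05 there were 25 higher and 20 lower.

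For miR-223-3p the log2 change was -1.32 (SE 0.09, limma adjusted p = 0.00086), with its probe mapped to chromosome X, 93438225 to 93438244 (mm9). That of miR-142a-3p was -0.64 (SE 0.09, limma adjusted p = 0.020), with its probe on chromosome 11, 87756904 to 87756925 (mm9). miR-511-3p was well above background on 3 of 3 control arrays and on 0 of 3 sunitinib arrays, with measured means of 4.58 and 2.61 (limma adjusted p = 0.0024), but the measured means differed by only -0.31 with normexp background correction (limma adjusted p = 0.144) and -0.32 in the scanner software's summed signal (limma adjusted p = 0.968). miR-532-5p changed by -0.54 (SE 0.09, limma adjusted p = 0.037). The summed signal instead gave 3.79, past the threshold as higher, although both probes of miR-532-5p were lower in sunitinib (-0.54 and -0.95). miR-3960 changed by 0.77 (SE 0.14), miR-5126 by 0.65 (SE 0.12), miR-2861 by 0.37 (SE 0.06) and miR-210-3p by 0.37 (SE 0.06), each with a limma adjusted p of 0.037. Of 21 alternatives, miR-3960 passed in 14, miR-5126 in 11, miR-210-3p in 8 and miR-2861 in 7. The probe of miR-210-3p maps to chromosome 7, 148407355 to 148407369 (mm9), and the files map none of the other 5 probes. All 3 sunitinib arrays lay on the same side of all 3 control arrays for each of the 8 miRNAs, as for 65 of the 237 tested. Chance gives 10% on average, but miRNAs on the same arrays are not independent, and the count of 65 was not tested against it. For 6 of the 8 a second probe, well above background on all 6 arrays, had a change in the same direction; the second probe was well above background on 0 of 6 arrays for miR-532-5p and on 3 of 6 for miR-511-3p.

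Values that did not pass were nearest for miR-139-5p among higher miRNAs (0.32, SE 0.07, limma adjusted p = 0.076) and for miR-362-3p among lower ones (-0.38, SE 0.08, limma adjusted p = 0.066), which passed in 3 of 21 alternatives. Of the 50 named miRNAs that did not pass, 11 passed in at least 1 alternative, and 5 of these, miR-139-5p, miR-30d-5p, miR-92a-3p, miR-150-5p and miR-212-3p, only when sunitinib replicate 2 was left out. Leaving out any control array left 0 higher and 2 lower miRNAs, leaving out sunitinib replicate 1 left 1 and 3, and leaving out sunitinib replicate 2 gave 12 and 5. With the slide row as a block, 0 were higher and only miR-223-3p was lower (-1.41, limma adjusted p = 0.020); the row with both groups holds 3 control arrays and 1 sunitinib array, within which the changes were -0.62 for miR-142a-3p, -0.45 for miR-532-5p, 0.52 for miR-3960, 0.40 for miR-5126, 0.40 for miR-2861 and 0.39 for miR-210-3p, and miR-511-3p was at least 2.18-fold lower.

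**Figure D1:**
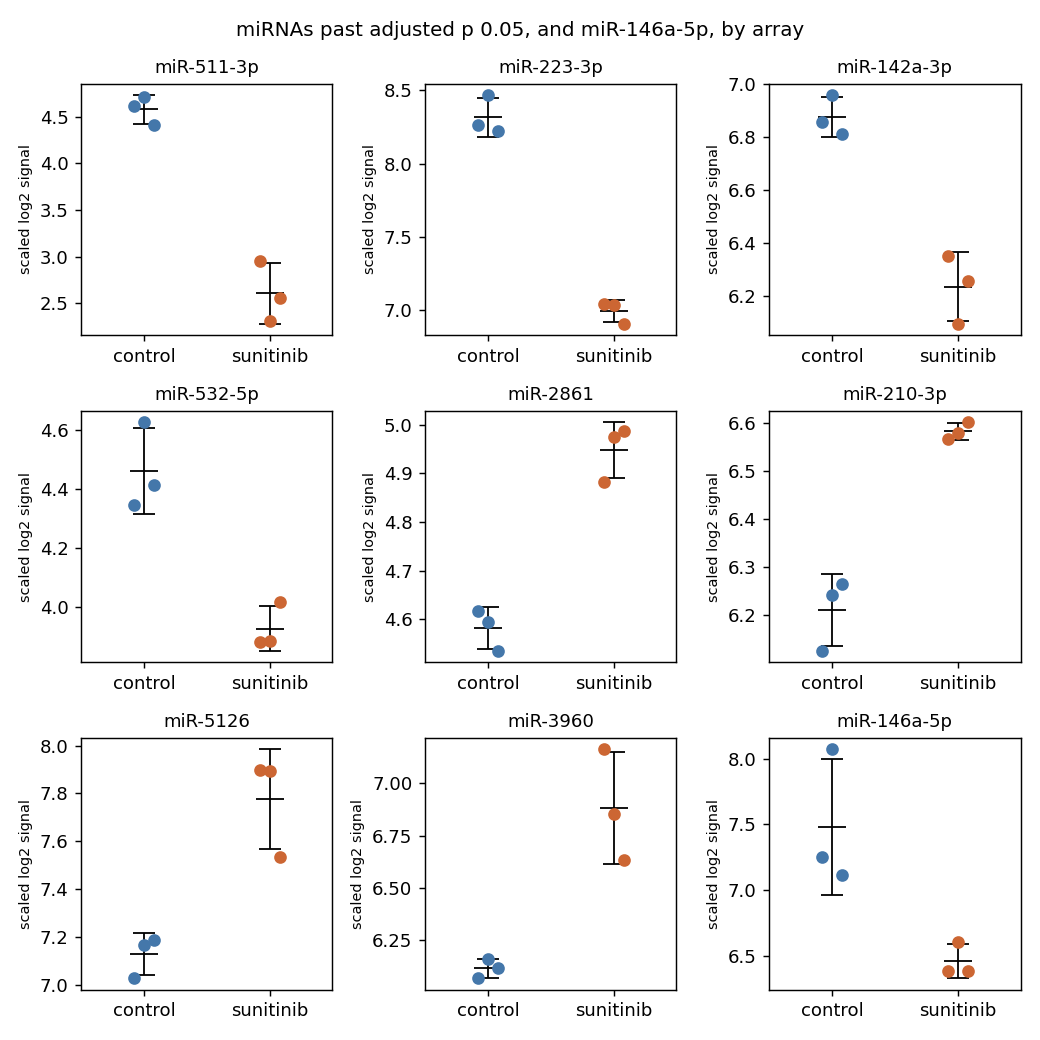
Scaled log2 signal (vertical axis, a separate range in each panel) of the 8 miRNAs past an adjusted p of 0.05 and of miR-146a-5p, by group. Points are arrays, and bars are the mean and SD of 3 arrays; in every panel the 3 sunitinib arrays lie on one side of the 3 control arrays.

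**Figure D2:**
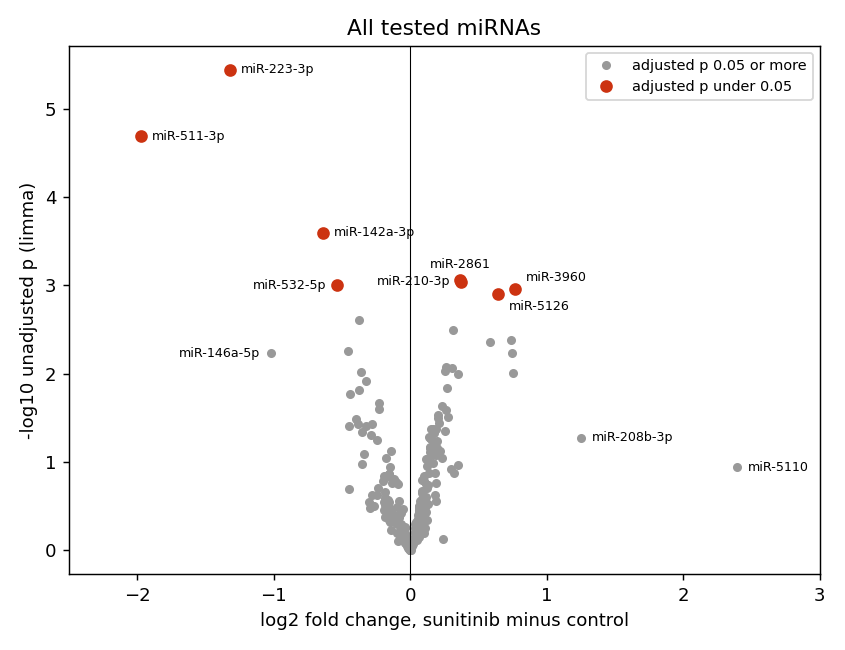
Log2 fold change (horizontal axis, sunitinib minus control) and -log10 unadjusted limma p (vertical axis) of the 237 tested miRNAs. Red points mark the 8 miRNAs with an adjusted p under 0.05, with miR-511-3p as measured; miR-5110 and miR-208b-3p have larger increases that did not pass.

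miR-146a-5p, a miRNA induced by NF-kB signalling, was 2.03-fold lower in sunitinib, with values of 7.25, 8.07 and 7.12 in control replicates 1 to 3 and 6.38, 6.61 and 6.38 in sunitinib replicates 1 to 3. Its log2 change of -1.02 (SE 0.25) did not pass (limma adjusted p = 0.093), although the sunitinib arrays lay below every control array. Its probe maps to chromosome 11, 43187908 to 43187925 (mm9). miR-146a-3p and miR-146b-5p were well above background on 0 of 6 arrays. The change passed in 4 of 21 alternatives, among them the deposited value table (-1.21, limma adjusted p = 0.021), and limma adjusted p ran from 6.9e-05 to 0.506 over the 21. The lowest came with scaling to the 75th percentile over all probes. Only 10.94% to 11.98% of an array's spots were well above background, so that percentile lies among probes that were not. With the slide row as a block it was -1.10 (limma adjusted p = 0.506).

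Of the 17 lists, 15 had at least 3 tested members, and camera found 0 shifted at an adjusted p of 0.05; 3 had an unadjusted p under 0.05, fry found 1, and with an estimated correlation the lowest adjusted p was 0.968. Among 7 tested leukocyte miRNAs, 2 fell (miR-223-3p and miR-142a-3p) and 5 did not pass, also when adjusted over the list alone; miR-150-5p, a lymphocyte miRNA, had a change of 0.35 and miR-155-5p of 0.15. The list's median was -0.05 (camera adjusted p = 0.197; fry adjusted p = 0.021); with the slide row as a block the median was 0.01 (camera adjusted p = 0.45). Of 4 tested erythroid miRNAs none passed, with 0.19 for miR-451a, 0.32 for miR-144-5p, -0.10 for miR-144-3p and -0.05 for miR-486a-5p. Of 5 tested NF-kB and innate immune miRNAs none passed over all miRNAs and 1, miR-146a-5p, was lower adjusted over the list alone. The others were miR-212-3p at -0.45, miR-132-3p at -0.35, miR-21a-5p at -0.19 and miR-155-5p, also in the leukocyte list, at 0.15. The list's median was -0.35 (camera adjusted p = 0.197), from -0.53 to -0.13 over the alternatives. With normexp miR-212-3p had -0.13 and miR-132-3p -0.10.

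The miR-29 family, which represses collagen genes, and the miR-30 family together had a median of 0.15 over 10 tested members, with 8 above 0 (camera adjusted p = 0.052, or 0.968 with an estimated correlation). The list passed in 6 of 23 alternatives, among them without sunitinib replicate 2 (median 0.22, camera adjusted p = 0.0095). Examples were miR-30d-5p at 0.27, miR-29a-3p at 0.26, miR-30a-3p at 0.19 and miR-30a-5p at 0.14, none past the threshold. Of 46 miRNAs of the imprinted Dlk1-Dio3 cluster on the arrays only 4 were tested. Their median was -0.38, or -0.37 with miR-154-5p at its bound (camera adjusted p = 0.052, or 0.968 with an estimated correlation). miR-379-5p and miR-154-5p entered the test only through the control arrays, which favours lower values in sunitinib. Where detection on all arrays was required, too few members remained for a list test, so the passes below do not exclude this bias. The cluster passed in 9 of 22 alternatives, among them the slide row as a block (median -0.50, camera adjusted p = 0.014). With the summed signal the median, with miR-154-5p as measured, was 0.31 and did not pass. That summed signal averaged 77.92 times the brightest probe for miR-379-5p and 4.884 times for miR-154-5p, against a median of 0.352 over detected miRNAs. Splits of the samples other than the real one each gave 1 to 3 lists past the threshold in camera. With normexp the cluster's median was -0.07 and did not pass, with -0.08 for miR-127-3p and -0.04 for miR-379-5p. Without normexp miR-127-3p had -0.45 (passing in 1 of 21 alternatives), miR-379-5p, well above background on 1 of 3 sunitinib arrays, -0.38 (in 3 of 20) and miR-494-3p -0.09. miR-154-5p was well above background on 0 of 3 sunitinib arrays and 1.28-fold lower at its bound. That bound carries no error and the measured change did not pass (limma adjusted p = 0.243), so no smallest fall is shown. Its measured change ran from -0.48 to 2.82 over the alternatives. Adjusted over the list alone 3 members were lower. The cluster's mean deviation was 0.14 in sunitinib replicate 2 against -0.38 and -0.25 in replicates 1 and 3.

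Of 8 tested muscle miRNAs none passed. miR-208b-3p, encoded within Myh7, had the widest spread among them, 5.03 ± 0.62 in control and 6.28 ± 0.95 in sunitinib (SD, n = 3 each), with a log2 change of 1.25 (SE 0.53, limma adjusted p = 0.263). It passed in 2 of 21 alternatives, with the percentile over all probes (1.27, limma adjusted p = 0.0018) and without sunitinib replicate 2 (1.82), and was 0.63 with normexp. miR-133a-5p had 0.13, miR-133a-3p 0.11 and miR-133b-3p 0.07. None of 16 hypertrophy miRNAs passed, with 0.17 for miR-23a-3p, also in the endothelial list. None of 9 endothelial miRNAs passed, with -0.15 for miR-222-3p and -0.18 for miR-126a-5p. None of 8 fibroblast miRNAs passed, with 0.19 for miR-10a-5p and -0.19 for miR-21a-5p. Both tested smooth muscle miRNAs, too few for a list test, did not pass, miR-145a-5p at -0.23 and miR-143-3p at -0.07.

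Of 5 hypoxia miRNAs, miR-210-3p rose, also adjusted over the list alone, while miR-503-5p had -0.36 and miR-322-5p 0.18. None passed among 9 miRNAs of the miR-17 and related clusters (miR-92a-3p 0.30, miR-25-3p 0.17), 9 of the let-7 family (let-7d-5p 0.13, let-7b-5p 0.14), 6 of the miR-15 family (miR-195a-5p 0.09), 5 p53-responsive miRNAs (miR-192-5p 0.16, miR-107-3p 0.08) and both tested liver, brain and epithelial miRNAs (miR-194-5p -0.02). Of 60 miRNAs numbered 1000 or higher 3 rose, miR-2861, miR-3960 and miR-5126, also adjusted over the list alone, and miR-8101 had 0.59, passing in 6 of 21 alternatives (0.23 to 0.96 over the 21). Camera adjusted p ran from 0.281 to 0.924 over the other 11 lists tested. Median and camera direction differed in sign for the hypertrophy (median 0.04, mean 0.03, camera down), hypoxia (median -0.07, mean 0.01, camera up) and p53 lists (median 0.02, camera down); for miRNAs numbered 1000 or higher the median was -0.02, the mean 0.04 and camera's direction down.

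**Figure D3:**
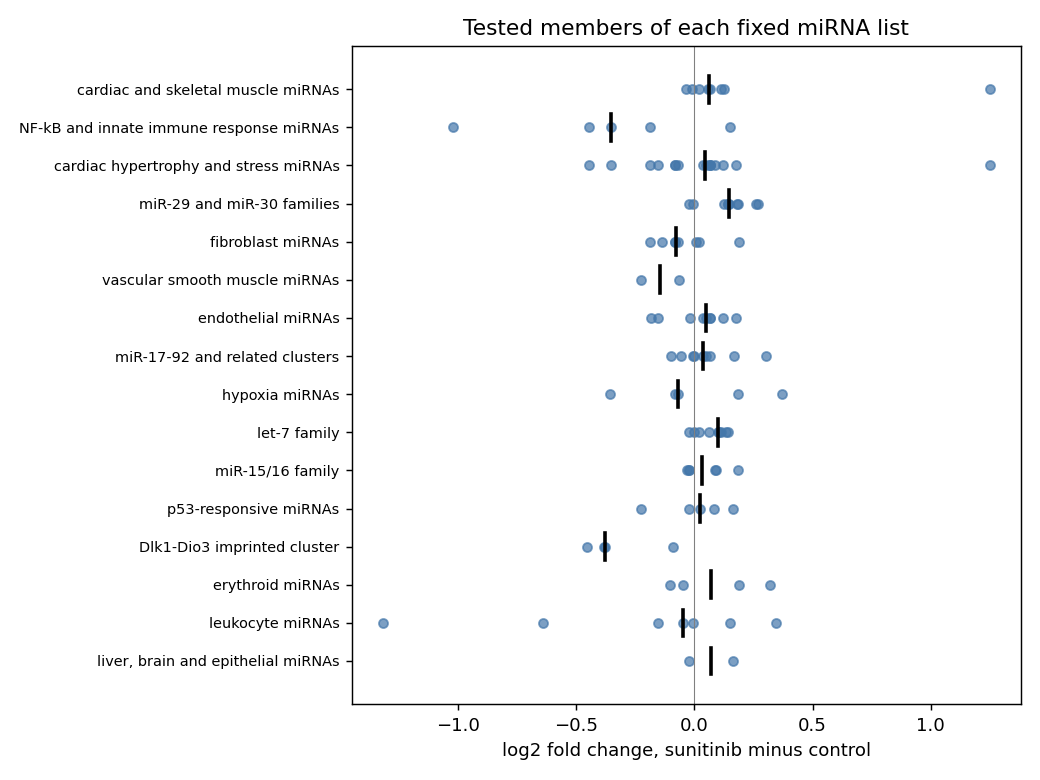
Log2 fold change (horizontal axis, sunitinib minus control) of each tested member (points) of the fixed lists, except the list defined by number, with the median of each list as a black bar. The leukocyte list holds miR-223-3p at -1.32 and miR-142a-3p at -0.64 beside members from -0.15 to 0.35.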

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

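All explanations tested here were chosen after the results were seen. Among miRNAs left out of the comparison because they were not well above background on all arrays of either group, miR-6538 was well above background on 2 of 3 sunitinib arrays and 0 of 3 control arrays, with means of 4.11 ± 0.33 and 2.98 ± 0.13 (SD, n = 3 each). miR-191-3p had the same detection, with 3.68 ± 0.11 and 3.45 ± 0.05. In the other direction, miR-1187, miR-3082-5p and miR-697 were well above background on 2 of 3 control arrays and 0 of 3 sunitinib arrays, with control and sunitinib means of 3.46 and 3.40, 3.61 and 3.18, and 3.49 and 3.31.

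The first pattern weighed was lower miR-223-3p, miR-142a-3p and miR-511-3p. Less blood left in the sunitinib samples would lower erythroid miRNAs by at least the 0.64 of miR-142a-3p, but their median was 0.0700 (SD 0.20, 4 miRNAs). A lower share of every non-muscle cell type would lower endothelial and fibroblast miRNAs too, and their median was 0.00718 (SD 0.12, 17 miRNAs). Most of these are also in the hypertrophy list and may not mark those cells alone, so the median cannot decide. Of members in the endothelial list only, miR-126a-3p had -0.02 and miR-126a-5p -0.18, short of the 0.64 fall. Slide row cannot be told apart from treatment, because only 1 sunitinib array shared a row with controls, where the median change was -1.41, or -1.13 with miR-511-3p at its bound; with the row as a block only miR-223-3p of the 3 passed (limma adjusted p = 0.020). A change in myeloid cells under sunitinib stays open and was not tested.

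The second pattern was higher miR-2861, miR-3960 and miR-5126, whose probes are 100%, 91.67% and 100% G and C. If GC-rich probes as such read higher, the other 5 tested miRNAs with probes of at least 80% GC would have risen too. Their median was 0.0297, yet they split, with miR-8101 at 0.59 and miR-8110 at 0.35 against -0.19 for miR-7686-5p, so GC content cannot be told apart from treatment here. Over all tested miRNAs GC share and log2 change had a Spearman rho of -0.0513, which shows no general trend but does not settle the most GC-rich probes. By the median and its SD of 0.318 alone GC content would have been argued against; that every such probe must also stay below 0.37 was required only after that value was seen. Slide row also stays open, with a within-row median of 0.40 from 1 sunitinib array.

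The third pattern was lower miR-146a-5p. A high control replicate 2 (8.07) as the whole cause is argued against by the change of -0.73 (SE 0.11) without it. Slide row stays open, with -1.10 within the shared row. An effect of sunitinib itself is the biological explanation the design gives and was not tested apart from these.

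The 6 samples can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 of the 10, the real one, gave as many as 4 miRNAs in a direction, against 0 in the others. For miR-146a-5p the real change was -1.02 and the largest size of any other split was 0.683, so 1 split was as large. For the lists the real count was 0 and the others ran from 1 to 3, so all 10 were as large. Any count matches 0, so this comparison was fixed in advance and decides nothing.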

How the results depend on the processing

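Any-probe detection was chosen after the data were seen; the other alternatives were planned. The 4 higher and 4 lower miRNAs became 2 and 2 with normexp, 8 and 5 with the percentile over all probes, 0 and 4 with quantile normalization, 1 and 3 without scaling, 4 and 7 with the mean of all probes, 7 and 2 with the summed signal, 0 and 3 without a filter, 6 and 7 with array weights and 0 and 1 with the slide row as a block. Leaving out a sample gave 0 to 12 higher and 2 to 5 lower. miR-223-3p passed in 21 of 21 alternatives, miR-142a-3p and miR-3960 in 14, miR-511-3p in 17 of 20, miR-5126 in 11, miR-210-3p in 8 and miR-2861 and miR-532-5p in 7, each in its own direction. miR-532-5p reversed to 3.79 with the summed signal and passed there as higher. The measured difference of miR-511-3p, not well above background in sunitinib, shrank to -0.31 with normexp and -0.32 with the summed signal, and that of miR-532-5p to -0.11 with normexp, without passing. Over the alternatives changes ran from -1.41 to -1.01 for miR-223-3p, -0.69 to -0.38 for miR-142a-3p, 0.48 to 0.89 for miR-3960, 0.40 to 0.76 for miR-5126, 0.13 to 0.42 for miR-2861 and 0.23 to 0.40 for miR-210-3p. miR-146a-5p stayed lower throughout (-1.23 to -0.70; -1.20 to -0.73 without a sample) and passed with the percentile over all probes (-1.002), no scaling (-1.02), the mean of all probes (-1.23) and the deposited table (-1.21). Shifted lists numbered 2 with normexp, 2 with the percentile over all probes, 2 with the median, 2 without scaling, 4 without a filter, 2 with array weights, 1 with the slide row as a block, 1 with fry and 0 to 3 without a sample. The Dlk1-Dio3 cluster passed in 9 of 22 alternatives, and had too few members for a list test where detection on all arrays was required. The miR-29 and miR-30 families passed in 6 of 23, the NF-kB and leukocyte lists in 3 each and the fibroblast list and the miRNAs numbered 1000 or higher in 1 each. With the summed signal the Dlk1-Dio3 median, with miR-154-5p as measured, was 0.31 and did not pass. Detected miRNAs stayed fewer in sunitinib in all 9 alternatives (-7.83 to -0.33, the last without control replicate 2). Values that changed sign with neither value past the threshold, 23 of 1194 for named miRNAs and 29 of 344 for lists, are not counted as reversals. The cause was not tested, except that testing more miRNAs or fewer samples weakens the adjustment or the estimate of spread by construction. Signal over background leaves only a bound for miR-511-3p and miR-154-5p.

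With the replicate number as a block, 0 miRNAs were higher, 2 lower and 1 list shifted, and miR-146a-5p had -1.02 (limma adjusted p = 0.151). Same-numbered samples' deviations correlated at 0.18, 0.22 and -0.06. Samples with different numbers were not compared in this way, so these values cannot decide whether the numbers pair samples.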

Other observations

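The hypothesis on arms was set before its test was run, and the other items were chosen after their values were seen. In the RefSeq table of GRCm38.p6 the precursors of miR-532, miR-362 and miR-500 lie within the gene Clcn5 on chromosome X. The tested arms had log2 changes of -0.54 (SE 0.09) for miR-532-5p, which passed, and of -0.38 (SE 0.08) for miR-362-3p and -0.32 (SE 0.09, limma adjusted p = 0.130) for miR-500-3p, which did not; in each the 3 sunitinib arrays lay below the 3 control arrays. The precursors of miR-2861 and miR-3960 are next to each other on chromosome 2, with 0 other miRNA precursors between them. miR-208a-3p, encoded within Myh6, had a change of -0.01 (SE 0.12) beside 1.25 (SE 0.53) for miR-208b-3p within Myh7.

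miR-5110 differed most between arrays of the same group, with 2.79 ± 2.46 in control and 5.18 ± 1.42 in sunitinib (SD, n = 3 each), and did not pass (limma adjusted p = 0.367). miR-208b-3p read 7.05, 5.22 and 6.57 in sunitinib replicates 1 to 3 and 4.88, 5.71 and 4.49 in control replicates 1 to 3. For miR-139-3p the scanner software's summed signal averaged 10920 where its brightest probe averaged 15.2, and 13 of 267 miRNAs detected by that software on all arrays had a ratio above 10.

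If the arms of a precursor change together, the log2 changes of 5p and 3p arms would correlate. Across 20 precursors with both arms tested, which are not independent replicates, Pearson r was -0.0558 and Spearman rho 0.04 (permutation p = 0.823), with the same sign in 10 of 20, and r was -0.14 without miR-3102 and miR-652. These data give no sign of joint change of the arms. None of the miRNAs past the threshold comes from these precursors, so joint change of arms in precursors with a clear change was not tested.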
